A study of Mus musculus with 12 samples.

How the data were processed

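RNA of 12 samples was measured on Illumina mouse bead arrays, 4 arrays each for the Neurosphere, LIF_NOG and BMP4 groups, with groups and replicate numbers taken from the titles and sample descriptions. Groups, comparisons, tests, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a later choice is marked as such.

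The deposited raw table gives, per the file headers, a non-normalized signal intensity for each probe on each array, as summarized over beads and not normalized between arrays. Beside each intensity the deposited raw table gives a detection p-value, computed before deposition against the negative controls of the same array. The submitters' processing notes name BeadStudio 3 and lumi 2.15.1 without a role for either. A second deposited table holds the authors' processed intensity values, which by their values are quantile normalized on a linear scale (the median of each column is 134) with no centring of genes. The transform and background step behind those values are not given in the sources used here. No per-sample column of the tables was left unused (0 columns).

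The rows of the deposited tables are not in 1 order throughout. In the raw table the signal of Neurosphere 1 had a median rank correlation of 0.0103 with the other columns, and in the authors' table the columns of Neurosphere 1, LIF_NOG 4 and BMP4 1 to 4 stand in another row order than the rest. Of these 6 arrays, the 5 other than Neurosphere 1 stand in 1 order in the raw table and in the other in the authors' table, with probes ranked alike, and so link both orders. Each of the 46630 rows of the authors' table was matched through them to the raw row (of 46643) nearest in rank, with a limit of 0.002 on the rank distance. This matched 46612 rows and left out 18, with a median rank distance of 0.000268 against 0.0306 to the second nearest row. On leaving out any 1 of the 5 linking arrays, between 99.86% and 99.99% of the matches were found again. After the move, the rank correlation of Neurosphere 1 with the other arrays of its group was 0.916 to 0.928, and the correlation between probes of the same gene on that array rose from 0.0055 to 0.304 over 4574 gene pairs. Probe IDs listed more than once in the raw table (11) were left out with the unmatched rows, which left 46602 probes with a value on all 12 arrays. The row order also divides the arrays into sets A and B, used as a block and as a restriction in alternatives chosen after the data were seen.

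Of these probes 29957 carried 1 gene symbol, 10 carried several and 16635 carried none. Symbols were compared with a GRCm38.p6 gene table through Entrez IDs, used for names only, and 0 symbols changed. Probes were kept when the detection p-value was under 0.05 on at least 4 of the 12 arrays, which kept 20304 probes, 15355 of them with 1 symbol. A gene with more than 1 kept probe (3343 genes) was represented by the probe with the highest mean, which gave 10785 genes. The 4949 kept probes without 1 symbol were tested apart. Mki67 and Aldh1l1, which the rule for named genes lists, are not analysed here.

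Signals were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp with negative controls inferred from the detection p-values, offset 16, then log2). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Group means were fitted to all 12 arrays with lmFit, contrasts were tested with contrasts.fit and eBayes (9 residual and 4.60 prior degrees of freedom), and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called at an adjusted p under 0.05. Fold changes are given with the moderated limma SE. For a called gene detected on no more than 2 of the 4 arrays of its dimmer group, or with a mean there under the mean detection floor of these arrays (log2 4.80 to 4.92 per array), values under the floor were replaced by the floor to give a lower bound, and no fold is given where both groups were undetected.

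Named genes were chosen by a fixed rule. Per comparison it takes the 6 largest positive and 6 largest negative fold changes among called genes that were detected on all 4 arrays of the higher group and did not overlap between groups. It adds the 3 called members of each gene list with the largest change, and, whatever their result, Gfap, Aqp4, S100b, Aldh1l1, Slc1a2, Aldoc, Gja1, Id1, Id3, Socs3, Nes, Egfr, Olig2, Mki67, Cdkn1a, Dcx, Cd44, Vim and Lcn2. It further adds 4 genes for each orientation of opposite change against Neurosphere, by their difference between BMP4 and LIF_NOG, and 4 per direction of the same change in both, by the smaller of both changes. For lists whose test did not pass fewer members are named.

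A total of 23 gene lists with 467 genes, of which 323 were measured, was drawn up: astrocyte markers, reactive astrocyte, BMP-SMAD target, gp130-STAT3 target, EGF-MAPK response, neural stem and progenitor, Notch pathway, cell cycle, CDK inhibitor, neuronal, oligodendrocyte progenitor, myelinating oligodendrocyte, microglia and macrophage, endothelial, smooth muscle and pericyte, fibroblast and collagen matrix, ependymal and ciliary, choroid plexus, cholesterol synthesis, glycolysis and hypoxia, interferon response, immediate early and heat shock, and synaptogenic and lectican matrix genes. Lists with at least 3 measured genes were tested with camera of limma at its preset correlation of 0.01, adjusted over all 66 tests, with camera at an estimated correlation and fry beside it. Members were also adjusted over their list alone. Genes called in both treatments against Neurosphere were counted by direction and set beside independent lists, 20 simulations of unchanged groups against the same controls, and the 6 ways to split the 4 Neurosphere arrays into pairs. Percent of probes detected and median signal were compared between groups with an exact permutation test.

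The median SE of a log2 fold change was 0.160, and the number of arrays limits the precision. The procedure was tested on simulated data drawn from a normal distribution with the mean and moderated variance of each of 10785 genes, with known changes added to 200 of them. For BMP4 against LIF_NOG it recovered 37.3% of 1.5-fold, 80.6% of 2-fold and 100% of 4-fold changes and called 8 unchanged genes. For LIF_NOG against Neurosphere the shares were 49.3%, 77.6% and 100% with 14 unchanged genes called, and for BMP4 against Neurosphere 38.8%, 92.5% and 100% with 12. A further small set of genes was shifted 2-fold for a list test. Spread and group size were the same in each comparison, so the shares differ by the draw of 66 or 67 genes per fold. Simulated genes varied independently with the same variance on every array, so the shares may differ in the real data.

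Alternatives covered background correction and normalization, the authors' values, the detection filter, the choice of probe, the arrays in the fit, a block by replicate number, array weights, the eBayes prior, stricter thresholds, split controls and leaving out each array. After the data were seen, the row-order set as a block, fits within 1 set, the raw table in its deposited row order and the authors' values with rows realigned were added.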

Results

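Neural stem cells were taken from the subventricular zone of CD1 mice at postnatal day 1 and grown as neurospheres (floating clusters kept in EGF). Cells were then differentiated with either of 2 cytokine treatments. RNA was measured on Illumina bead arrays, 12 in all, 4 for each of 3 groups. The Neurosphere arrays hold RNA of sorted neurosphere cells kept in EGF at 20 ng/ml. The LIF_NOG arrays hold cells treated for 7 days with LIF, a cytokine that signals through the gp130 receptor and STAT3, at 20 ng/ml, together with the BMP antagonist noggin at 250 ng/ml. The BMP4 arrays hold cells treated for 7 days with the growth factor BMP4, which signals through SMAD proteins, at 20 ng/ml. EGF was lowered to 1 ng/ml in both treated groups. Per the labels, cells of both treated groups carried a retrovirus with GFP driven by the Gfap promoter, Neurosphere cells carried a control GFP retrovirus, and GFP-positive cells were sorted before differentiation. The series text speaks of RNA from GFP-expressing cells after 7 days, and the files do not say whether cells were sorted again at harvest, which would select for Gfap promoter activity. Virus, EGF dose and time in culture therefore changed together with the cytokines in each comparison with Neurosphere, and Gfap is the gene whose promoter drove the reporter used for sorting. The labels do not say whether the 4 samples of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

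Between 38.6% and 40.2% of probes were detected on the Neurosphere arrays, between 39.3% and 41.5% on the LIF_NOG arrays and between 39.2% and 42.0% on the BMP4 arrays. The means were 39.4% ± 0.673, 40.2% ± 0.947 and 40.2% ± 1.26 (SD, n = 4). None of these differences passed an exact two-sided permutation test, with p = 0.971 for BMP4 against LIF_NOG, p = 0.229 for LIF_NOG against Neurosphere and p = 0.343 for BMP4 against Neurosphere, where 0.0286 is the smallest p that 4 against 4 allows. Median raw signal per array lay between 69.0 and 80.9. By the 2 row orders of the deposited tables, brought into 1 before any comparison, the arrays fall into a set A (Neurosphere 2 to 4 and LIF_NOG 1 to 3) and a set B (Neurosphere 1, LIF_NOG 4 and BMP4 1 to 4). These sets may mark separate processing, so each comparison is given also with the set as a block and within 1 set. Ranges of adjusted p run over the alternatives with matched rows, which leave out the 2 that take a table with its rows as deposited.

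The first principal component held 65.5% of the variance and placed the Neurosphere arrays between -54.1 and -49.9, the LIF_NOG arrays between -22.7 and -5.61 and the BMP4 arrays between 64.3 and 73.4. The second held 19.1% and set the LIF_NOG arrays apart from both other groups. LIF_NOG 2 stood apart from its group, with a score of 11.0 on the second component against 36.0 to 49.8 for the other LIF_NOG arrays, and a score of -41.2 on the third component, which held 4.48% of the variance. Within LIF_NOG, 30 of 32 cell cycle genes and 17 of 18 cholesterol synthesis genes were highest on that array, as were 15 of 26 reactive astrocyte genes and 12 of 18 glycolysis and hypoxia genes. Of 29 astrocyte markers, 12 were lowest and 8 highest there. Gfap was at 8.77 on LIF_NOG 2 against 11.01 to 12.33 on the other LIF_NOG arrays, and Hes5 was lowest there too, while Ccdc3, Cd44, Lcn2, Sphk1, Kcnc4 and Pfkp were highest.

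**Figure D1:**
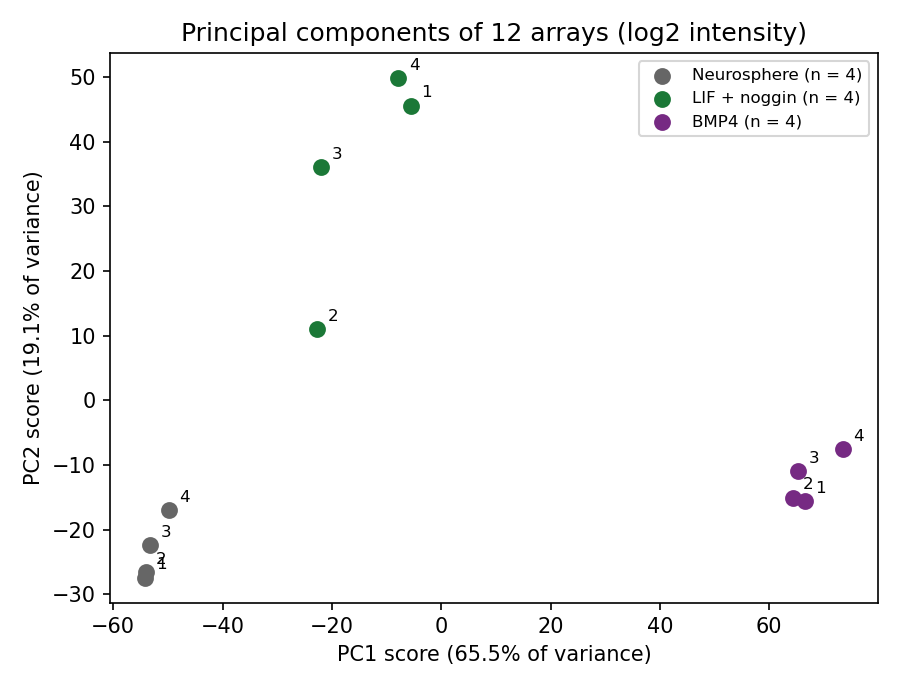
Scores of the 12 arrays on the first and second principal components of normalized log2 intensity, with points coloured by group and numbered by replicate. The 4 Neurosphere arrays lie at -54.1 to -49.9 on the horizontal axis, the 4 BMP4 arrays at 64.3 to 73.4, and LIF_NOG 2 lies at 11.0 on the vertical axis, below the other LIF_NOG arrays at 36.0 to 49.8.

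LIF_NOG was compared with Neurosphere to find which genes differ once neurosphere cells have spent 7 days with LIF and noggin. Gfap, the intermediate filament protein of astrocytes, was at least 63.8-fold higher in LIF_NOG (adjusted p = 7.85e-06, n = 4 arrays per group), and at least 106.3-fold without LIF_NOG 2. It was detected on 1 of the 4 Neurosphere arrays. Serpina3n, a serine protease inhibitor induced in reactive astrocytes, was at least 78.5-fold higher, the lipid carrier gene Clu 39.9-fold higher (log2 fold change 5.32 ± 0.32, SE, n = 4), and Apoe, which encodes the main lipoprotein of astrocytes, 37.2-fold higher (5.22 ± 0.34). The transcription factor gene Fos rose 45.8-fold (5.52 ± 0.21) and its relative Fosb at least 39.01-fold. Kcnc4, a voltage-gated potassium channel gene, was at least 18.5-fold lower and was detected on 1 of the 4 LIF_NOG arrays. Here and below, a fold given as at least a value is a lower bound against the detection floor. The other 5 genes named for the largest drops were Tmem158 (-3.32 ± 0.33), Hs3st2 (at least 6.26-fold lower), Tnnt1 (-2.54 ± 0.24), Diras2 (-2.42 ± 0.27) and Efs (-2.41 ± 0.21), with Hs3st2 detected on 1 of the 4 LIF_NOG arrays. All 12 of these genes had limma adjusted p between 3.82e-09 and 3.26e-05.

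Of 10785 genes tested, 3569 passed the adjusted p threshold in LIF_NOG against Neurosphere, 1785 of them higher and 1784 lower. At least 2-fold changes numbered 722 up and 434 down. With the row-order set as a block 3409 genes passed, and within set A (3 arrays against 3) 1693 passed. Scaling arrays to a common median in place of quantile normalization put 62.4% of the calls on the higher side, against 50.0% here.

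Astrocyte markers rose as a group with LIF and noggin: of 29 measured, 19 rose, 0 fell and 10 did not pass, and 19 rose when adjusted over the list alone. The camera test of this list gave an adjusted p of 1.54e-07, and an adjusted p of 0.0768 with an estimated correlation. Aqp4, the water channel of astrocyte endfeet, rose by 3.92 ± 0.20 on the log2 scale. The glutamate transporter gene Slc1a2 (0.61 ± 0.14) and the gap junction gene Gja1 (0.70 ± 0.16) rose by less. Aldoc, which encodes a brain aldolase, rose by 0.97 ± 0.29 with an adjusted p of 0.0181, but the call was lost without Neurosphere 1 (0.0582), Neurosphere 2 (0.0577), LIF_NOG 1 (0.0629) or LIF_NOG 4 (0.0571), with changes of 0.82 to 0.88, and within set A (0.74 ± 0.31, adjusted p = 0.138), with adjusted p from 0.000354 to 0.138 over alternatives with matched rows. S100b was undetected on all 8 arrays of both groups. Without LIF_NOG 2, the array that stood apart, 18 markers rose and 1 fell.

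Reactive astrocyte genes, those induced in astrocytes by injury or inflammation, had 13 of 26 measured members higher, 1 (S100a10) lower and 12 not passing, with 14 higher and 1 lower when adjusted over the list alone. Camera gave this list an adjusted p of 2.17e-05, and an adjusted p of 0.310 with an estimated correlation. Osmr, a cytokine receptor subunit that pairs with gp130, rose at least 9.13-fold, and the metalloproteinase inhibitor gene Timp1 rose by 3.29 ± 0.37. Vim, the intermediate filament gene of immature and reactive astrocytes, rose by 0.86 ± 0.12. The hyaluronan receptor gene Cd44 rose by 0.96 ± 0.23, a call lost with the mean of its probes (0.42, adjusted p = 0.0725) and within set A (1.03 ± 0.33, adjusted p = 0.0732), with 0.00271 to 0.0732 over alternatives with matched rows. Lcn2 did not pass (mean 5.43 ± 1.93 against 4.42 ± 0.0156, SD, n = 4, adjusted p = 0.338): it was detected on LIF_NOG 2 at 8.32 and on no other LIF_NOG array. Without LIF_NOG 2, 13 members of the list rose and 3 fell.

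Target genes of gp130 and STAT3 had 10 of 19 measured members higher, 1 (Bcl6) lower and 8 not passing (10 and 2 when adjusted over the list alone). Their camera adjusted p was 0.000278, and the adjusted p with an estimated correlation was 0.0847. Socs3, a feedback inhibitor of this pathway, rose by 4.33 ± 0.33 and Junb, an AP-1 gene, by 3.81 ± 0.22. No member was lower by limma (0 genes) without Neurosphere 1, 2 or 4, LIF_NOG 1, 3 or 4 or BMP4 1, and 2 were lower without LIF_NOG 2 or BMP4 4. Of 15 BMP-SMAD target genes, 4 rose, 2 fell and 9 did not pass (5 and 2 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.193). The risers were Hey1, Id4 (2.35 ± 0.30), Hes1 (1.68 ± 0.20) and Bmper, of which Hey1 and Hes1 also stand in the Notch list. Id1 and Zeb1 were the genes that fell. Id1, an inhibitor of bHLH transcription factors, fell by 0.90 ± 0.19, a call lost with the mean of its probes (-0.37, adjusted p = 0.104) and within set A (-0.77 ± 0.26, adjusted p = 0.0811), with 0.000667 to 0.104 over alternatives with matched rows. Id3 differed by 0.04 ± 0.16 (adjusted p = 0.902).

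Cell cycle genes fell almost throughout the list in LIF_NOG: of 32 measured, 0 rose, 30 fell and 2 did not pass, with 31 lower when adjusted over the list alone. Camera gave an adjusted p of 8.48e-12, and an adjusted p of 0.389 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, fell by 2.19 ± 0.43 on the log2 scale, the mitotic kinase gene Aurka by 2.00 ± 0.38 and the cyclin gene Ccne2 at least 4.304-fold. Ccne2 was detected on 2 of the 4 LIF_NOG arrays. Within set A it was at least 3.56-fold lower, and its call was lost (adjusted p = 0.0529, and 7.22e-07 to 0.0529 over alternatives with matched rows). On LIF_NOG 2, 30 of the 32 cell cycle genes were the highest of their group, and without it 31 fell. Of 7 CDK inhibitor genes, 0 rose, 1 (Cdkn2d) fell and 6 did not pass, and the list did not pass (adjusted p = 0.614). Of these 7, 2 fell without LIF_NOG 2 or LIF_NOG 3, and 1 rose without LIF_NOG 1. Cdkn1a, the gene of the inhibitor p21, differed by -0.53 ± 0.26 (adjusted p = 0.135), and passed without LIF_NOG 3 (-0.77, adjusted p = 0.0234, and 0.0234 to 0.361 over alternatives with matched rows).

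Genes of myelinating oligodendrocytes had 8 of 13 measured members higher in LIF_NOG, 2 (Car2 and Tspan2) lower and 3 not passing, the same counts as when adjusted over the list alone. Camera gave an adjusted p of 0.00819, and an adjusted p of 0.125 with an estimated correlation, with 0.000902 to 0.947 over alternatives with matched rows. Without Neurosphere 1 to 3, LIF_NOG 1 or LIF_NOG 4, 1 member was lower. Cldn11, a tight junction protein of myelin, rose 19.4-fold (4.28 ± 0.42). Opalin, a myelin membrane protein gene, rose by 2.42 ± 0.53 and Mbp, the gene of myelin basic protein, by 1.99 ± 0.36. Opalin was detected on 3 of the 4 Neurosphere arrays and rose by 3.13 without LIF_NOG 2. Within set A the call of Opalin was lost (1.99 ± 0.74, adjusted p = 0.107, and 1.61e-06 to 0.107 over alternatives with matched rows). Of 14 oligodendrocyte progenitor genes, 1 (Omg) rose, 3 (Nkx2-2, Olig2 and Cspg4) fell and 10 did not pass, and the list did not pass (adjusted p = 0.440). No member was higher by limma (0 genes) without Neurosphere 1 or 2 or LIF_NOG 1 or 4, and 4 were lower without LIF_NOG 4. Olig2, a transcription factor gene of that lineage, fell by 0.88 ± 0.22.

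Some neuronal genes and most ependymal genes measured were called higher. Of 22 neuronal genes, 6 rose, 0 fell and 16 did not pass (6 and 0 when adjusted over the list alone), with a camera adjusted p of 0.0264 and an adjusted p of 0.440 with an estimated correlation. Without LIF_NOG 2, 9 neuronal genes rose and 1 fell, and without Neurosphere 4, 6 rose and 1 fell. The neuronal call was lost without Neurosphere 3 (0.0508) or Neurosphere 4 (0.0764), and its adjusted p ran from 0.00339 to 0.440 over alternatives with matched rows. Dcx, a microtubule protein gene of young neurons, rose by 3.17 ± 0.38, the RNA-binding protein gene Celf4 by 2.71 ± 0.25, and Gad1, the gene of a GABA-synthesizing enzyme, by 1.92 ± 0.43, with Dcx detected on 3 of the 4 Neurosphere arrays. Of 8 ependymal and ciliary genes, 7 rose, 0 fell and 1 did not pass (7 and 0 when adjusted over the list alone), with a camera adjusted p of 0.000498 and an adjusted p of 0.310 with an estimated correlation. The ciliary genes Fam183b and Tekt1 rose at least 3.51-fold and 2.81-fold, and Rsph1 rose by 1.62 ± 0.33.

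Immediate early genes led another list that rose, with 7 of 10 measured members of the immediate early and heat shock list higher, 0 lower and 3 not passing (8 and 0 when adjusted over the list alone). By camera this list had an adjusted p of 7.79e-06, and an adjusted p of 0.0768 with an estimated correlation. Zfp36, an RNA-decay factor gene, rose by 3.32 ± 0.35, and Dnajb1 was the heat shock gene among the risers. Of 13 Notch pathway genes, 6 rose, 0 fell and 7 did not pass (8 and 0 when adjusted over the list alone), with a camera adjusted p of 0.00171 and an adjusted p of 0.304 with an estimated correlation. The Notch target gene Hes5 rose by 3.37 ± 0.64, at 8.50 on LIF_NOG 2 against 11.9 to 12.5 on the other LIF_NOG arrays (4.28 without LIF_NOG 2), and its call was lost within set A (2.86 ± 0.84, adjusted p = 0.0561, and 3.72e-08 to 0.0561 over alternatives with matched rows). Interferon response genes had 6 of 14 members higher, 1 (Rsad2) lower and 7 not passing, the same as when adjusted over the list alone, with a camera adjusted p of 0.0387 and an adjusted p of 0.343 with an estimated correlation. Ifi27 (2.12 ± 0.18), Irf1 (1.57 ± 0.22) and Irf9 (1.43 ± 0.20) rose most, with Irf1 detected on 3 of the 4 Neurosphere arrays. That list's call was lost without Neurosphere 4 (0.0764) or LIF_NOG 2 (0.132), and ran from 0.00401 to 0.343 over alternatives with matched rows. In it 0 members were lower by limma without Neurosphere 1 or 2, and 2 were lower without Neurosphere 4 or LIF_NOG 2. Cholesterol synthesis genes had 0 of 18 members higher, 9 lower and 9 not passing (0 and 11 when adjusted over the list alone), with a camera adjusted p of 0.000498 and an adjusted p of 0.501 with an estimated correlation. Within LIF_NOG 17 of the 18 were highest on LIF_NOG 2, and 13 fell without it, while 5 fell without Neurosphere 3, Neurosphere 4, LIF_NOG 1 or LIF_NOG 4. Among these enzymes and carriers Lss fell by 1.32 ± 0.36, Stard4 by 1.26 ± 0.29 and Fdps by 1.13 ± 0.32. The call of Lss was lost with the mean of its probes (-0.59, adjusted p = 0.0510, and 0.000840 to 0.0510 over alternatives with matched rows) and that of Fdps within set A (-0.85 ± 0.27, adjusted p = 0.0727, and 0.000692 to 0.0727).

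The other lists did not pass in LIF_NOG against Neurosphere. Neural stem and progenitor genes had 2 members (Vim and Prom1) higher, 2 (Gli3 and Rfx4) lower and 12 not passing (adjusted p = 0.756). This became 1 higher and 1 lower without Neurosphere 1 or LIF_NOG 1, 1 higher without Neurosphere 2 or 4, and 1 lower without Neurosphere 3 or LIF_NOG 4. Nes, the intermediate filament gene of neural stem cells, differed by 0.24 ± 0.25 (adjusted p = 0.508), and the EGF receptor gene Egfr by -0.01 ± 0.13 (adjusted p = 0.979). EGF-MAPK response genes moved both ways, with Dusp5, Phlda1, Ier3 and Egr1 higher and Etv4, Spry4, Dusp6 and Etv5 lower among 13 (adjusted p = 0.787). Their median (-0.24) and camera pointed down, and their mean (0.09) and fry's test pointed up. Setting undetected genes to their bound left this median and those below unchanged, except where given. Glycolysis and hypoxia genes had 3 higher and 2 lower of 18 (0.756), synaptogenic and matrix genes 3 higher and 1 lower of 12 (0.755), and fibroblast and collagen genes 1 higher and 2 lower of 12 (0.756). Glycolysis and hypoxia genes had 3 higher and 7 lower without LIF_NOG 2, 1 and 1 without LIF_NOG 1, and 3 and 4 without BMP4 4. Synaptogenic genes had 3 lower without LIF_NOG 2 and 2 without Neurosphere 4. Of fibroblast genes 0 were lower by limma without Neurosphere 1 or 2 or LIF_NOG 1 or 4, 1 was lower without Neurosphere 3, and 2 were higher without LIF_NOG 3 or 4. The median of the synaptogenic list was -0.08, while its mean was 0.23 and camera pointed up. Endothelial genes had 2 higher and 0 lower of 8 (0.787), smooth muscle and pericyte genes 0 higher and 2 lower of 6 (0.944), and choroid plexus genes 0 higher and 1 lower of 5 (0.668). These fell to 1 endothelial gene higher without any 1 Neurosphere array or LIF_NOG 4, to 1 smooth muscle gene lower without any 1 Neurosphere array, LIF_NOG 1, 2 or 4 or BMP4 2, and to 0 choroid plexus genes lower by limma without any 1 Neurosphere array or LIF_NOG 1 or 4. The endothelial list had a median of -0.10 and a mean of 0.22, with camera pointing up, and the smooth muscle list a median of 0.18 (0.11 with undetected genes at their bound) and a mean of -0.18, with camera pointing down. Of the microglia and macrophage genes Lyz2 alone was measured, and it was undetected on all 8 arrays of both groups.

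**Figure D2:**
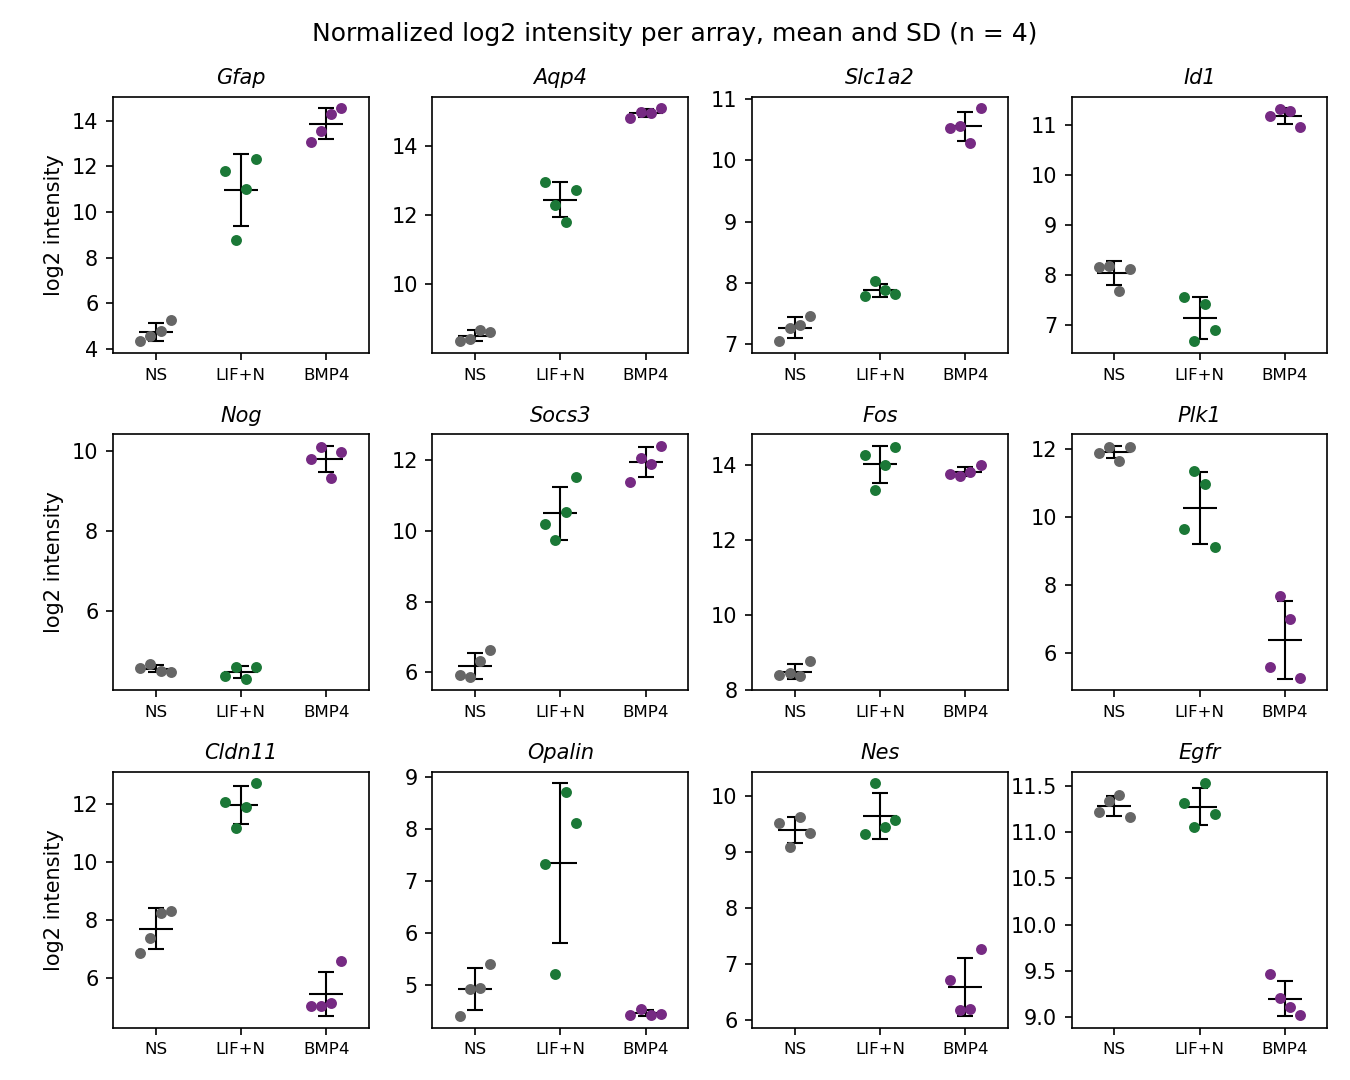
Normalized log2 intensity of 12 named genes on each array, with the mean and SD of the 4 arrays of each group (NS, Neurosphere; LIF+N, LIF_NOG). Gfap lies near background in Neurosphere (mean 4.73), at 10.98 in LIF_NOG and at 13.87 in BMP4, while Cldn11 is highest in LIF_NOG (11.96) and Nog rises from background in BMP4 alone (9.80).

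BMP4 was compared with Neurosphere to find which genes differ after 7 days with BMP4. Gfap was at least 473.5-fold higher in BMP4 (adjusted p = 2.64e-08, n = 4 arrays per group), and was detected on 1 of the 4 Neurosphere arrays. Serpinf1, which encodes the secreted factor PEDF, was 506-fold higher (8.98 ± 0.15, SE, n = 4), the secreted protein gene Ccdc3 354-fold higher (8.47 ± 0.62), and the lipid droplet gene Cidea at least 219.6-fold higher, with Cidea detected on 1 of the 4 Neurosphere arrays. Serpina3n rose at least 136.5-fold and Rgs9, a regulator of G protein signalling, 119-fold (6.89 ± 0.27). The largest drops were in Pimreg, a mitotic gene, which was at least 56.6-fold lower and detected on 2 of the 4 BMP4 arrays, and Bcas1, an early myelinating oligodendrocyte gene, which was at least 47.0-fold lower. Cdca8 (-5.69 ± 0.47), Plk1 (-5.52 ± 0.53) and Cenpa (-5.49 ± 0.37), which act in mitosis, and the matrix protein gene Fbln2 (-5.67 ± 0.35) fell by similar amounts. All 12 genes had limma adjusted p between 1.15e-13 and 9.48e-07.

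In BMP4 against Neurosphere 5854 of 10785 genes passed, 2867 higher and 2987 lower, and 1500 rose and 1274 fell by at least 2-fold. With the row-order set as a block 4685 genes passed. Within set B, where the 4 BMP4 arrays face Neurosphere 1, assumed to vary like the other arrays, 3805 passed.

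Nearly the whole astrocyte list rose with BMP4: of 29 markers, 27 rose, 0 fell and 2 (Fgfr3 and Slc1a3) did not pass, the same as when adjusted over the list alone. The camera adjusted p was 5.52e-11, and the adjusted p with an estimated correlation was 0.0768. Apoe rose by 6.47 ± 0.34, Aqp4 by 6.44 ± 0.20, Clu by 6.04 ± 0.32, Slc1a2 by 3.28 ± 0.14, Aldoc by 2.69 ± 0.29 and Gja1 by 2.06 ± 0.16. S100b, a calcium-binding protein of mature astrocytes, rose at least 3.12-fold. Reactive astrocyte genes had 14 of 26 members higher, 3 (S100a10, Fkbp5 and B3gnt5) lower and 9 not passing, the same as when adjusted over the list alone, with a camera adjusted p of 0.00945 and an adjusted p of 0.501 with an estimated correlation. The small heat shock protein gene Hspb1 rose by 6.76 ± 0.32, the sphingosine kinase gene Sphk1 by 4.54 ± 0.43 and Cd44 by 2.67 ± 0.23. Vim rose by 0.47 ± 0.12 (adjusted p = 0.00437), but not under median scaling (0.21, adjusted p = 0.355), with the mean of its probes (0.29, adjusted p = 0.108), with the row-order set as a block (0.40, adjusted p = 0.0679) or within set B (0.45 ± 0.24, adjusted p = 0.188), with 0.000930 to 0.355 over alternatives with matched rows. Lcn2 did not pass (mean 5.84 ± 1.10 against 4.42 ± 0.0156, SD, n = 4, adjusted p = 0.126), and passed with only the 8 arrays compared (0.00962), with array weights (0.0174) and without LIF_NOG 2 (adjusted p = 0.00485, and 0.00485 to 0.351 over alternatives with matched rows), an array that enters the shared estimate of the spread.

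BMP-SMAD target genes all passed in BMP4 against Neurosphere, 13 of 15 higher and 2 (Zeb1 and Tgif1) lower, also when adjusted over the list alone. In the camera test the adjusted p was 3.06e-05, and the adjusted p with an estimated correlation was 0.0768. Nog, the gene of the BMP antagonist noggin, rose at least 30.02-fold. Id4 rose by 4.79 ± 0.30, Id2 by 4.54 ± 0.24, Id1 by 3.13 ± 0.19 and Id3 by 2.29 ± 0.16. Target genes of gp130 and STAT3 had 11 of 19 members higher, 2 (Cebpd and Myc) lower and 6 not passing, the same as when adjusted over the list alone, although no LIF was added. Their camera adjusted p was 0.00248, and the adjusted p with an estimated correlation was 0.160. Socs3 rose by 5.77 ± 0.33 and Junb by 3.67 ± 0.22, and the transcription factor gene Tfcp2l1 rose at least 7.36-fold.

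Cell cycle genes fell with BMP4 in 31 of 32 measured members, with 0 higher and 1 not passing, the same as when adjusted over the list alone. By camera the adjusted p was 4.12e-14, and the adjusted p with an estimated correlation was 0.324. Rrm2, detected on 3 of the 4 BMP4 arrays, fell by 5.26 ± 0.43 on the log2 scale, next to the drops of Plk1 and Cenpa given above. Cdkn1a differed by 0.47 ± 0.26 (adjusted p = 0.141), and CDK inhibitor genes as a list, with 1 (Cdkn2b) higher, 4 lower and 2 not passing, did not pass (adjusted p = 0.338). In that list 0 members were higher by limma without any 1 Neurosphere array or BMP4 1, 2 or 4. Immediate early and heat shock genes had 6 of 10 members higher, 0 lower and 4 not passing (7 and 1 when adjusted over the list alone), with a camera adjusted p of 0.00772 and an adjusted p of 0.304 with an estimated correlation. Without Neurosphere 3 or LIF_NOG 2, 1 member was lower. Fos rose by 5.33 ± 0.21 and the phosphatase gene Dusp1 by 3.67 ± 0.18, and Fosb rose at least 8.26-fold (at least 4.63-fold without BMP4 4), at 10.45 on BMP4 4 against 7.01 to 7.27 on the other BMP4 arrays, with its call lost within set B (at least 8.46-fold, adjusted p = 0.0540, and 2.10e-06 to 0.0540 over alternatives with matched rows). Synaptogenic and lectican matrix genes had 8 of 12 members higher, 1 (Wnt7a) lower and 3 not passing, the same as when adjusted over the list alone, with a camera adjusted p of 0.00418 and an adjusted p of 0.0768 with an estimated correlation. Of these 0 were lower by limma without Neurosphere 1 or 4 or BMP4 1 or 2. Sparcl1, which encodes hevin, a secreted promoter of synapse formation and also an astrocyte marker, rose by 4.33 ± 0.20, Sparc, its antagonist, detected on 3 of the 4 Neurosphere arrays, by 3.03 ± 0.49 and the proteoglycan gene Bcan by 2.57 ± 0.24.

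The remaining lists did not pass in BMP4 against Neurosphere. Oligodendrocyte progenitor genes had 2 (C1ql1 and Tnr) higher, 8 lower and 4 not passing of 14 (adjusted p = 0.0762). Pdgfra, the receptor gene of these progenitors, fell by 2.98 ± 0.20, Sox10, a transcription factor gene of the lineage, was at least 5.01-fold lower and Olig2 fell by 1.51 ± 0.22. Myelinating oligodendrocyte genes had 1 (Sirt2) higher and 4 lower of 13 (0.194). Neural stem and progenitor genes had 3 (Pax6, Vim and Lhx2) higher and 5 (Sox11, Nes, Rfx4, Egfr and Tead2) lower of 16 (0.382), with a median of 0.02, a mean of -0.55 and camera pointing down. Nes fell by 2.80 ± 0.25 and Egfr by 2.08 ± 0.13. EGF-MAPK response genes had 2 higher and 7 lower of 13 (0.161), Notch pathway genes 6 higher and 3 (Nrarp, Dll3 and Dll1) lower of 13 (0.235), and neuronal genes 7 higher and 5 (Map2, Stmn3, Ina, Dlx5 and Neurod1) lower of 22 (0.756), where Dcx differed by 0.16 ± 0.38 (adjusted p = 0.758). Without BMP4 1 or 2, 3 neuronal genes were lower. Glycolysis and hypoxia genes had 7 higher and 2 (Adm and Hk2) lower of 18 (0.119), interferon response genes 7 higher and 2 (Gbp3 and Rsad2) lower of 14 (0.131), cholesterol synthesis genes 2 (Sc5d and Pmvk) higher and 5 lower of 18 (0.382) and ependymal genes 4 higher and 0 lower of 8 (0.119). Choroid plexus genes had 2 higher and 0 lower of 5 (0.338), fibroblast and collagen genes 5 higher and 1 (Pdgfra) lower of 12 (0.324), endothelial genes 2 higher and 1 lower of 8 (0.769), and smooth muscle and pericyte genes 2 higher and 1 lower of 6 (0.787). Without single arrays some of these counts moved: 1 cholesterol gene was higher without Neurosphere 1 to 3 or BMP4 1 or 4, and 1 choroid plexus gene without any 1 Neurosphere array, LIF_NOG 3 or BMP4 1, 2 or 4. Smooth muscle genes had 2 lower without Neurosphere 1, LIF_NOG 2 or BMP4 4, and fibroblast genes 2 lower without LIF_NOG 2. The endothelial and smooth muscle lists had a median of -0.02 each, with means of 0.31 and 0.04 and camera pointing up. Lyz2, the lysozyme gene and the 1 microglia and macrophage gene with a kept probe, rose at least 12.6-fold.

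**Figure D3:**
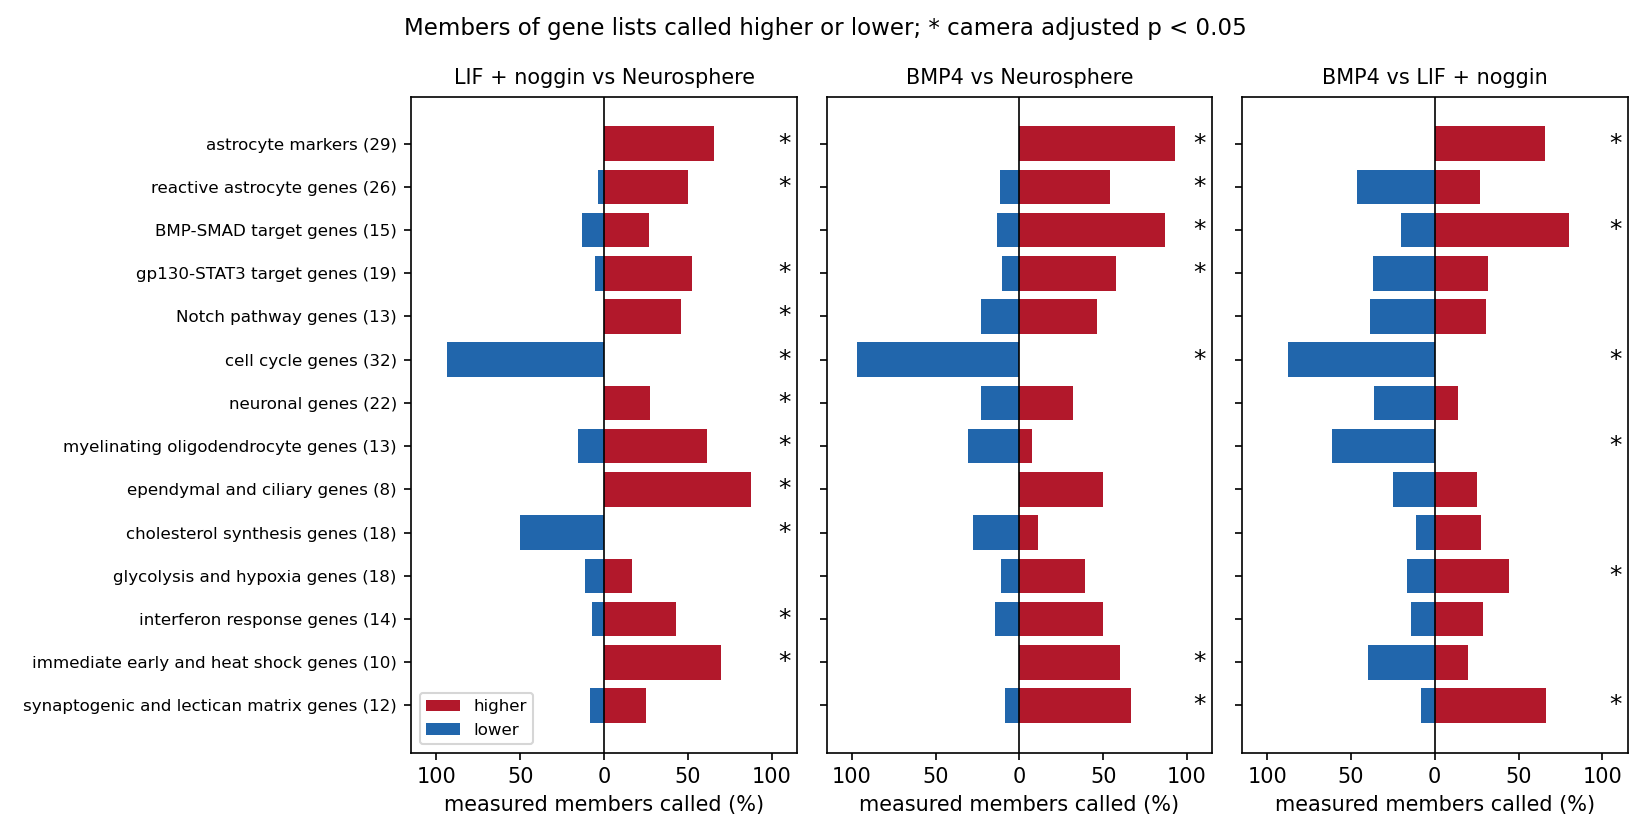
Share of the measured members of 14 gene lists that were called higher (red, right) or lower (blue, left) in each comparison, in percent, for the lists that passed in any comparison, with the number of measured members in brackets and an asterisk where the camera adjusted p passed. Astrocyte markers lie to the right in all 3 comparisons and cell cycle genes to the left.

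BMP4 was compared with LIF_NOG to find which genes differ between cells given either treatment. Both groups carried the same virus and the same EGF dose. Serpinf1 was 503-fold higher in BMP4 (8.97 ± 0.15, SE, n = 4 arrays per group) and Cidea at least 238-fold higher. Papss2, which encodes a sulfate donor synthetase, was at least 82.3-fold higher, the small GTPase gene Diras2 102-fold higher (6.68 ± 0.27), Ccdc3 92.1-fold higher (6.53 ± 0.62, and 171.5-fold without LIF_NOG 2) and Stum at least 61.6-fold higher, with Stum detected on 1 of the 4 LIF_NOG arrays. On the LIF_NOG side, Cldn11 was 92.0-fold higher there than in BMP4 (-6.52 ± 0.42) and Bcas1 at least 64.1-fold higher. Fbln2 (-5.65 ± 0.35), the activity-induced transcription factor gene Egr4 (-5.65 ± 0.42), the channel subunit gene Cacng5 (at least 29.3-fold lower) and Myt1, a zinc finger gene of the neural lineage (-4.99 ± 0.47, and -5.59 without LIF_NOG 2), were the other genes named for being lower in BMP4, where Cacng5 was detected on 1 of 4 arrays. All 12 had limma adjusted p between 1.17e-13 and 2.02e-06.

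Of 10785 genes, 4736 passed between BMP4 and LIF_NOG, with 2233 higher and 2503 lower in BMP4, and 985 and 845 of them by at least 2-fold. With the row-order set as a block 3369 genes passed. Within set B, where the 4 BMP4 arrays face LIF_NOG 4, assumed to vary like the other arrays, 2314 passed. The 24 list calls of the 3 comparisons held with the set as a block. Within set B the BMP4 comparisons rest on 1 array in 1 group, so calls there are not counted as support. With an estimated correlation, 0 of the 24 passed by camera of limma.

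Astrocyte markers were higher in BMP4 than in LIF_NOG in 19 of 29 cases, lower in 0 and did not pass in 10 (19 and 1 when adjusted over the list alone). Without LIF_NOG 2, 19 were higher and 2 lower. The camera adjusted p was 2.90e-06, and the adjusted p with an estimated correlation was 0.0768. The zinc transporter gene Slc39a12 was higher by 4.95 ± 0.29, Sparcl1 by 4.49 ± 0.20, Slc1a2 by 2.67 ± 0.14, Aqp4 by 2.52 ± 0.20 and Gja1 by 1.36 ± 0.16, and S100b was at least 3.19-fold higher. Gfap was 7.42-fold higher (2.89 ± 0.59, adjusted p = 0.00122) and 4.46-fold without LIF_NOG 2. It was higher by 2.42 ± 0.78 with the row-order set as a block (adjusted p = 0.0331), but it did not pass within set B (1.54 ± 0.53, adjusted p = 0.0840), with 0.000210 to 0.0840 over alternatives with matched rows. Aldoc was higher by 1.72 ± 0.29, and did not pass within set B either (1.32 ± 0.41, adjusted p = 0.0620, and 2.18e-05 to 0.0620 over alternatives with matched rows).

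BMP-SMAD target genes differed throughout, 12 of 15 higher in BMP4 and 3 (Zeb1, Hes1 and Tgif1) lower, also when adjusted over the list alone. Camera gave an adjusted p of 7.68e-05, and an adjusted p of 0.0776 with an estimated correlation. Nog was at least 30.7-fold higher, and Id1 was higher by 4.03 ± 0.19, Id2 by 3.90 ± 0.24 and Id3 by 2.26 ± 0.16. Target genes of gp130 and STAT3 moved both ways, with Tfcp2l1, Pim3, Socs3, Bcl6, Fgl2 and Socs1 higher, Klf4, Cebpd, Osmr, Stat3, Bcl3, Cish and Myc lower and 6 of 19 not passing (camera adjusted p = 0.975, where camera pointed down and fry's test up). Tfcp2l1 was higher by 2.80 ± 0.34, the kinase gene Pim3 by 1.79 ± 0.14 and the transcription factor gene Klf4 was lower (-2.01 ± 0.21), with Tfcp2l1 detected on 3 of the 4 LIF_NOG arrays. Socs3 was higher by 1.45 ± 0.33 (adjusted p = 0.00249), a call lost with the row-order set as a block (1.07, adjusted p = 0.0692) and within set B (0.43 ± 0.36, adjusted p = 0.460), with 0.000121 to 0.460 over alternatives with matched rows.

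Cell cycle genes were lower in BMP4 than in LIF_NOG in 28 of 32 cases, higher in 0 and did not pass in 4, with 29 lower when adjusted over the list alone. Camera gave an adjusted p of 1.95e-10, and an adjusted p of 0.431 with an estimated correlation. Cenpa was lower (-4.07 ± 0.37), as were the mitotic kinase genes Plk1 (-3.89 ± 0.53) and Cdk1 (-3.21 ± 0.45), with the call of Plk1 lost within set B (-2.73 ± 0.86, adjusted p = 0.0660, and 9.46e-06 to 0.0660 over alternatives with matched rows). CDK inhibitor genes had 2 (Cdkn2b and Cdkn1a) higher, 3 (Cdkn1c, Cdkn2a and Cdkn2c) lower and 2 not passing (adjusted p = 0.516). In this list 1 member was higher without Neurosphere 1, 2 or 4, LIF_NOG 1, 3 or 4 or BMP4 1, 2 or 4. Cdkn1a was higher by 1.00 ± 0.26, a call lost within set B, where it was higher by 1.27 ± 0.39 (adjusted p = 0.0625, and 0.000888 to 0.0625 over alternatives with matched rows).

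Myelinating oligodendrocyte genes were lower in BMP4 than in LIF_NOG in 8 of 13 cases (Cldn11, Bcas1, Opalin, Mbp, Trf, Mag, Enpp6 and Cnp), higher in 0 and did not pass in 5, the same as when adjusted over the list alone. Camera gave an adjusted p of 0.00107, and an adjusted p of 0.0768 with an estimated correlation, with 3.66e-05 to 0.728 over alternatives with matched rows. Opalin was at least 5.58-fold lower (at least 9.13-fold without LIF_NOG 2). Oligodendrocyte progenitor genes had 2 (C1ql1 and Tnr) higher, 7 lower and 5 not passing of 14 (adjusted p = 0.175). Sox10 was at least 8.18-fold lower and Pdgfra was lower too (-3.22 ± 0.20). Olig2 was lower in BMP4 (-0.63 ± 0.22, adjusted p = 0.0340), but the call was lost without LIF_NOG 3 (-0.59, adjusted p = 0.0803), LIF_NOG 4 (-0.57, 0.0811), BMP4 2 (-0.65, 0.0579) or BMP4 3 (-0.37, 0.0866), within set B (-0.81 ± 0.44, 0.247), without a detection filter (0.0676) and with only the 8 arrays compared (0.0704), with 0.00626 to 0.247 over alternatives with matched rows.

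Synaptogenic and lectican matrix genes had 8 of 12 members higher in BMP4, 1 (Thbs2) lower and 3 not passing, the same as when adjusted over the list alone. By camera the adjusted p was 0.00196, and the adjusted p with an estimated correlation was 0.0768. The glypican gene Gpc6 was at least 4.39-fold higher, detected on 1 of the 4 LIF_NOG arrays, and Sparc was higher by 1.93 ± 0.49. Without BMP4 3, 2 members were lower. Glycolysis and hypoxia genes had 8 of 18 members higher, 3 (Hk2, Adm and Ndrg1) lower and 7 not passing, the same as when adjusted over the list alone, with a camera adjusted p of 0.0340 and an adjusted p of 0.501 with an estimated correlation. The glucose transporter gene Slc2a1 was higher by 2.56 ± 0.28, the growth factor gene Vegfa by 2.24 ± 0.36 and the phosphofructokinase gene Pfkp by 2.13 ± 0.24. The call of this list was lost without LIF_NOG 4 (0.0738) or BMP4 4 (0.0526), and ran from 0.00109 to 0.501 over alternatives with matched rows.

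The reactive astrocyte list moved both ways between the treatments, with 7 of 26 members higher in BMP4, 12 lower and 7 not passing (camera adjusted p = 0.787, where camera pointed down and fry's test up). Sphk1 (4.92 ± 0.43), Hspb1 (3.91 ± 0.32) and Cd44 (1.72 ± 0.23) were higher in BMP4 with Aspg, Tgm1, Ptx3 and H2-T23. Timp1 was lower (-2.79 ± 0.37), as were Emp1, Cd109, Cp, Fkbp5, Psmb8, Serping1, S100a10, Osmr, Amigo2, B3gnt5 and Vim. The difference in Vim was -0.39 ± 0.12 (adjusted p = 0.0161), lost without BMP4 1 (-0.35, adjusted p = 0.0501) or BMP4 2 (-0.34, 0.0529) and within set B (-0.51 ± 0.24, 0.174), with 0.00146 to 0.174 over alternatives with matched rows. Lcn2 did not pass (mean 5.84 ± 1.10 against 5.43 ± 1.93, SD, n = 4, adjusted p = 0.707), and passed without LIF_NOG 2 (at least 1.975-fold higher, adjusted p = 0.0128, and 0.0128 to 0.992 over alternatives with matched rows).

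Of the other lists, none passed between BMP4 and LIF_NOG. Neural stem and progenitor genes had 3 (Pax6, Gli3 and Lhx2) higher and 7 lower of 16 (adjusted p = 0.119), among them Nes (-3.05 ± 0.25), the transcription factor gene Sox11 (-2.81 ± 0.17) and Egfr (-2.08 ± 0.13). EGF-MAPK response genes had 0 higher and 6 lower of 13 (0.0645), led by the cyclin gene Ccnd1 (-3.92 ± 0.40), and 2 higher and 5 lower without LIF_NOG 2. Notch pathway genes had 4 (Dner, Notch3, Hey1 and Hey2) higher and 5 (Nrarp, Hes5, Dll1, Dll3 and Hes1) lower of 13 (0.648), with Nrarp at -3.50 ± 0.17 and Hes5 at -3.13 ± 0.64 (-4.05 without LIF_NOG 2). Neuronal genes had 3 higher and 8 lower of 22 (0.234), where the granin gene Scg2 (3.00 ± 0.22) and the homeobox gene Dlx2 (2.36 ± 0.26) were higher with Snap25 and Dcx was lower (-3.01 ± 0.38), with Scg2 on 3 of the 4 LIF_NOG arrays and Dcx on 3 of the 4 BMP4 arrays detected. Immediate early and heat shock genes had 2 (Dusp1 and Hsph1) higher and 4 (Fosb, Atf3, Dnajb1 and Jun) lower of 10 (0.567). Cholesterol synthesis genes had 5 higher and 2 (Ebp and Mvk) lower of 18 (0.128), interferon response genes 4 higher and 2 (Gbp3 and Psmb9) lower of 14 (0.352), and fibroblast and collagen genes 6 higher and 1 (Pdgfra) lower of 12 (0.205), with 2 lower without LIF_NOG 4. Of cholesterol synthesis genes, 9 were higher and 0 lower by limma without LIF_NOG 2, 4 and 0 without LIF_NOG 3, 5 and 0 without BMP4 2, 4 and 1 without BMP4 1 and 6 and 1 without BMP4 3. Ependymal genes had 2 (Mia and Tppp3) higher and 2 (Tekt1 and Dynlrb2) lower of 8 (0.611), choroid plexus genes 2 higher and 0 lower of 5 (0.128), endothelial genes 1 (Slco1a4) higher and 1 (Flt1) lower of 8 (0.900), and smooth muscle and pericyte genes 2 (Rgs5 and Tagln) higher and 2 (Acta2 and Higd1b) lower of 6 (0.701). Ependymal genes had 1 higher and 4 lower without LIF_NOG 2 or 3, 1 lower without LIF_NOG 1 or 4 or BMP4 1, and 1 higher without BMP4 3 or 4. Endothelial genes had 0 lower by limma without BMP4 1, 2 or 3, and 1 smooth muscle gene was lower without LIF_NOG 1 or 2 or BMP4 1 or 2. Lyz2 was at least 12.9-fold higher in BMP4.

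Both treatments were then set side by side against Neurosphere. Gfap, Serpina3n, Fos and Clu rose most in both, and Hs3st2, Cdca7, Dhh and Tuba1c fell most in both. Hs3st2, a heparan sulfate sulfotransferase gene, was at least 6.26-fold lower in LIF_NOG and at least 5.98-fold lower in BMP4, where it was detected on 2 of 4 arrays. Cdca7, a cell division gene, changed by -2.40 ± 0.34 and -3.07 ± 0.34, and the tubulin gene Tuba1c by -2.38 ± 0.54 and -3.65 ± 0.54. Dhh, a hedgehog ligand gene, changed by -2.40 ± 0.51 in LIF_NOG and was at least 12.1-fold lower in BMP4. Without LIF_NOG 2 the changes in LIF_NOG were -3.11 for Dhh and -3.02 for Tuba1c. Within set A the LIF_NOG calls of Dhh (-1.98 ± 0.64, adjusted p = 0.0726, and 1.63e-07 to 0.0726 over alternatives with matched rows) and Tuba1c (-1.96 ± 0.60, adjusted p = 0.0632, and 1.81e-05 to 0.0632) were lost.

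In all, 1183 genes rose in both treatments and 1423 fell in both, where independent lists of these sizes would share 475 and 494. Simulated unchanged groups, with the Neurosphere values simulated as well, gave 0 such genes by limma in each of 20 simulations. With no change present this follows from the threshold, and it does not measure what shared controls add to real changes. With the 4 Neurosphere arrays split into pairs, each serving 1 comparison, the 6 splits gave between 1541 and 1796 genes changed the same way, against 2606 with shared controls, 2190 with the row-order set as a block and 1119 within 1 set. Across genes, which are not independent replicates, the fold changes of both comparisons correlated at 0.616 (0.504 in simulated unchanged groups, 0.559 to 0.610 with split controls). Their covariance was 0.489 against 0.0185 in simulation, a difference of 0.471. The sign was the same in both for 73.0% of all genes, against 66.7% in simulation. Of the genes changed the same way, 1372 also differed between BMP4 and LIF_NOG.

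Another 179 genes changed in opposite directions against Neurosphere, 92 of them up in LIF_NOG and down in BMP4 and 87 the other way, where independent lists would share 494 and 474, and split controls gave between 70 and 116 in all. Cldn11 (4.28 ± 0.42 in LIF_NOG, -2.25 ± 0.42 in BMP4), Egr4 (3.73 ± 0.42, -1.92 ± 0.42), the related Egr3 (2.79 ± 0.35, -1.69 ± 0.35) and Myt1 (1.39 ± 0.47, -3.60 ± 0.47) rose in LIF_NOG and fell in BMP4. Diras2 (-2.42 ± 0.27, 4.26 ± 0.27), the mitochondrial gene Chchd10 (-2.28 ± 0.33, 3.58 ± 0.33) and Kcnc4 (at least 18.5-fold lower, 1.22 ± 0.25) fell in LIF_NOG and rose in BMP4. Cidea rose in BMP4 and was called lower in LIF_NOG (mean 4.38 ± 0.07 against 4.81 ± 0.31, SD, n = 4, adjusted p = 0.0426). No fold is given there, as it was undetected on all 4 LIF_NOG arrays and detected on 1 Neurosphere array. That call of Cidea was lost on leaving out Neurosphere 1, 2 or 4, any LIF_NOG array or BMP4 2 (adjusted p from 0.0513 to 0.115), with the row-order set as a block (0.0552) and within set A (0.148). It was also lost without background correction, with normexp without controls, in the authors' processed values, without a detection filter, with only the 8 arrays compared, with the replicate block, with array weights and with a trended prior, with 0.0252 to 0.288 over alternatives with matched rows. The LIF_NOG call of Myt1 (adjusted p = 0.0347, and a change of 1.99 without LIF_NOG 2) was lost without Neurosphere 1 to 3 or LIF_NOG 1, 3 or 4 (changes of 1.03 to 1.32, adjusted p from 0.0797 to 0.108) within set A (0.96 ± 0.56, 0.293), without a detection filter (0.0845) and with only the 8 arrays compared (0.0683), with 4.23e-05 to 0.293 over alternatives with matched rows. In BMP4 the calls of Cldn11 (-1.40 ± 0.59, adjusted p = 0.112, and 8.24e-06 to 0.112 over alternatives with matched rows) and Egr3 (-0.98 ± 0.37, adjusted p = 0.0840, and 0.000342 to 0.0840) were lost within set B. The call of Egr4 was lost in the authors' processed values (-0.93 ± 0.40, adjusted p = 0.0738, and 1.56e-05 to 0.0738).

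**Figure D4:**
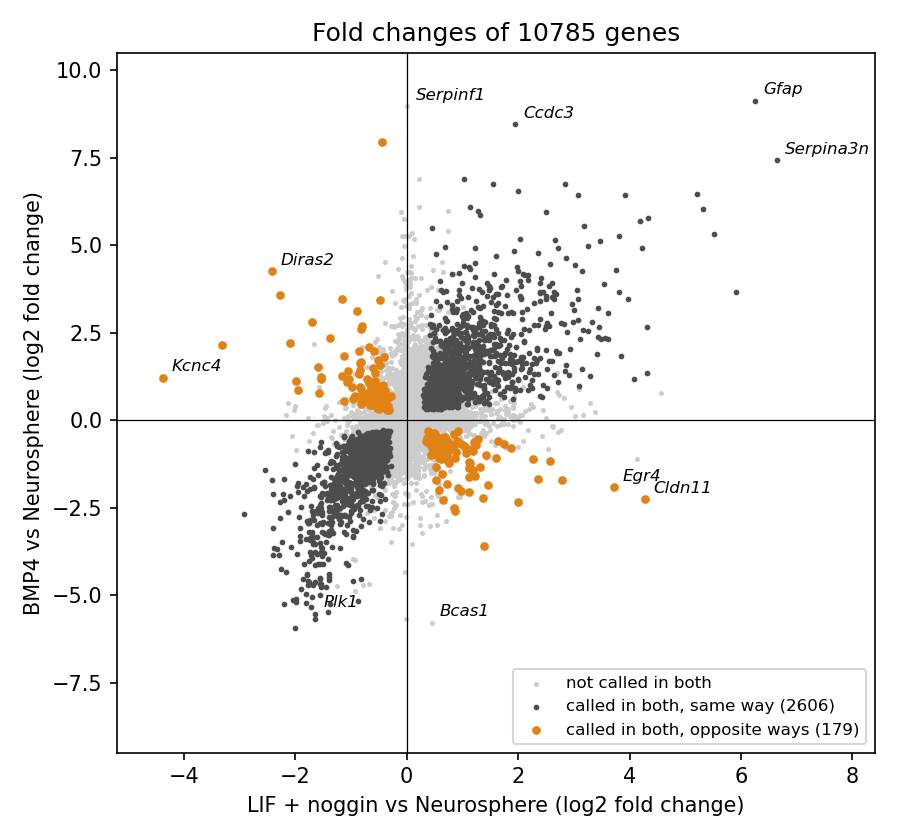
Log2 fold change of 10785 genes in LIF_NOG against Neurosphere (horizontal) and in BMP4 against Neurosphere (vertical), with genes called in both in the same direction in dark grey (2606) and in opposite directions in orange (179). Both axes share the 4 Neurosphere arrays, so part of the slope comes from the shared controls.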

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

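Most tests below were fixed before their result was seen. The exchange of a label and the leaving out of single LIF_NOG arrays for the myelin genes were chosen after the pattern was seen.

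A Dixon test on each of 191 named genes and 3 measures of array quality, per group, looked for 1 array far from the other 3. Of 582 groups of 4 arrays, 42 (7.22%) had such an array, where chance alone gives about 1 in 20. BMP4 4 held 10 of these values, LIF_NOG 2 held 9, Neurosphere 3 held 8 and Neurosphere 4 held 6.

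On LIF_NOG 2, log2 intensity was high for Ccdc3 (10.32, others 6.45 to 7.08), Cd44 (10.89, others 9.78 to 9.88), Flt1 (8.919, others 5.70 to 6.16), Kcnc4 (5.826, others up to 4.70), Lcn2 (8.322, others 4.41 to 4.51), Pfkp (7.594, others 6.44 to 6.45), Rgs5 (4.531, others 4.37 to 4.39) and Sphk1 (7.599, others 5.76 to 5.83). Hes5 was low there (8.496, others 11.87 to 12.49). The Rgs5 values of LIF_NOG all lay under the detection floor. On LIF_NOG 3, Celf4 was the lowest of its group (8.381), and on LIF_NOG 1, Dner was the highest (12.45). On BMP4 4, Aspg (7.006), Cldn11 (6.592), Fosb (10.45), H2-T23 (5.631), Junb (9.75), S100b (7.56), Tagln (6.658) and Timp1 (9.02) were high, and Sox11 (9.008) and Sphk1 (10.21) were low.

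In the other BMP4 arrays, the values that stood apart were Opalin (4.549) and Bcl6 (10.33) on BMP4 2, Pdgfra on BMP4 1 (5.663), and Tnnt1 (8.19) and Omg (9.173) on BMP4 3. On Neurosphere 3, Cdkn2b (7.443), Dcx (4.522), Dnajb1 (10.79), Dusp1 (8.968), Id1 (7.674) and Papss2 (4.297) were low and Prom1 (10.55) and Tuba1c (10.87) were high. Neurosphere 4 stood apart in Adm (7.917), Bmper (7.21), Egr4 (8.598), Fdps (13.18), Myt1 (9.588) and Sirt2 (8.906), Neurosphere 1 in Bcan (8.946) and Neurosphere 2 in Stum (5.278). Among these values, Opalin on BMP4 2 and Dcx and Papss2 on Neurosphere 3 lay under the detection floor.

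Of genes called against Neurosphere in both treatments, 179 moved in opposite directions. All 179 passed between BMP4 and LIF_NOG too, which largely follows from how they were chosen and is no separate result. Among 4949 kept probes without a single gene symbol, 1597 differed between BMP4 and LIF_NOG (696 higher, 901 lower), 1184 between LIF_NOG and Neurosphere (504 and 680) and 2121 between BMP4 and Neurosphere (892 and 1229).

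The number of genes was set beside that of all 35 ways to divide the 8 arrays of a comparison into 4 and 4. For each comparison 1 split, the real one, gave as many genes by limma. BMP4 against LIF_NOG gave 4736 genes against 185 in the highest other split (5393 against 2243 at unadjusted p). LIF_NOG against Neurosphere gave 3569 against 909 (4552 against 3300), and BMP4 against Neurosphere 5854 against 0 (6246 against 1502). The split with 909 genes placed LIF_NOG 2 with Neurosphere 1 to 3. Of the 34 other splits, 31, 33 and 34 gave no gene. Mixed splits put the difference between groups into the spread, which lowers their counts. The rank of the real split was therefore largely set beforehand, and 1 of 35 is the smallest share possible. Chance between cultures cannot be excluded in this way, as the samples of a group may be technical.

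LIF_NOG 2 lay between the Neurosphere and other LIF_NOG arrays on the second component, but apart from all on the third. Its place between them may come from neurosphere cells or RNA in that sample. If so, at most 10% of the genes in which it deviates at least 2-fold would lie outside the span between both by over 0.5 log2, and over 30% if not. Only genes bright in any group were counted. Of 544 such genes 176, or 32.35%, lay outside (95% interval 28.6% to 36.4%, which takes genes as independent). The interval lay above the 10% set for mixing, which argues against mixing alone for these 176 genes. It reached below 30%, so a part played by mixing was left open. LIF_NOG 1, 3 and 4, each set against the rest of its group, had 94.7% of 76, 37.7% of 61 and 93.4% of 197 such genes outside. An exchanged label was tested too. Over the genes tested, 0 Neurosphere arrays correlated more highly with a LIF_NOG array (at most 0.958) than with another Neurosphere array (at least 0.990). No biological explanation was tested, as the labels give LIF_NOG 2 no group of its own.

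The arrays of BMP4 all belong to row-order set B and those of LIF_NOG mostly to set A, so a processing batch could stand behind part of the difference between them. A batch would move Neurosphere 1, the Neurosphere array of set B, away from the others along that difference with a slope of at least 0.5, and under 0.1 if not. The slope was 0.01246, against 0.00669, -0.0132 and -0.00600 for the other Neurosphere arrays, and so lay under the value set beforehand for no batch. LIF_NOG 4, the LIF_NOG array of set B, had a slope of 0.00344 against its group, where the other LIF_NOG arrays had 0.0442, 0.0376 and -0.0853. Each of these slopes rests on 1 array, and a smaller effect of the set, or one on the BMP4 arrays alone, was not excluded.

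Of 13 myelin genes measured, 8 were called higher in LIF_NOG than in BMP4. The list call was lost with an estimated correlation (camera adjusted p = 0.0768) and under the strict filter. A single LIF_NOG array or cells of the oligodendrocyte lineage in the cultures might explain this difference. Leaving out each LIF_NOG array in turn, at least 8 members of the list were still called lower in BMP4, so no single array carried the difference. Per the labels, GFP-positive cells with a reporter driven by the Gfap promoter were sorted before treatment, and the make-up of the cultures after 7 days is not given. Cells of that lineage in varying numbers would move the 8 members that rose against Neurosphere together over the LIF_NOG arrays, with a mean correlation over 0.5, and under 0 if not. The mean correlation was 0.1052, where random gene sets had a median of 0.135 and 56.3% of them were as high, so the test cannot tell. Expression of myelin genes by the astrocytes themselves, as an effect of the treatment, was not tested.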

How the results depend on the processing

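Most alternatives left the results as reported. Those chosen after the data were seen are named above. Quantile normalization without background correction gave 4682 genes for BMP4 against LIF_NOG, 3559 for LIF_NOG against Neurosphere and 5757 for BMP4 against Neurosphere, where 4736, 3569 and 5854 are reported. Median scaling gave 4360, 3042 and 5419, normexp without controls 4704, 3579 and 5780, and the authors' values with rows realigned 4596, 3458 and 5668. Without a detection filter the counts were 4665, 3410 and 5872, with the mean of probes 4702, 3652 and 5890, and with only the 8 arrays of each comparison 4194, 3467 and 6109. Array weights gave 5289, 4912 and 6670, and a trended and robust prior 4729, 3550 and 5858. The strict filter gave 3669, 2835 and 4572, with fewer genes tested by construction. With the row-order set as a block the counts were 3369, 3409 and 4685.

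Leaving out each array in turn gave 4213 to 5062 genes for BMP4 against LIF_NOG, with the lowest count without LIF_NOG 3 and the highest without LIF_NOG 2. For LIF_NOG against Neurosphere the range was 2803 to 4351 and for BMP4 against Neurosphere 5413 to 6170. The number of lists that passed was 22 to 25, where 24 are reported, and the number of genes changed the same way was 2091 to 2979, where 2606 is reported.

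Of 179 fold changes given for single genes, between 175 and 179 kept their direction and call under each new fit chosen before the data were seen, apart from the authors' values with rows as deposited and the strict filter. Of the values the strict filter tested, 111 of 111 were the same. Within 1 row-order set 157 did and 22 were weaker. Of these 22, 6 had a change at least as large as with all arrays and 20 had a larger SE, and what else differs between the sets was not tested.

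Counts fell under stricter thresholds by construction. With an absolute log2 fold change of at least 1 the counts were 1830, 1156 and 2774, in the order above. At the stricter adjusted p 2209 genes passed for LIF_NOG against Neurosphere, next to 3483 and 4762 for the others. Of 169 called values of single genes, 162 passed the stricter adjusted p and 158 were at least 2-fold. Those lost at the stricter adjusted p were Vim and Olig2 in BMP4 against LIF_NOG and Cidea, Myt1, Aldoc, Lss and Fdps in LIF_NOG against Neurosphere.

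With an estimated correlation, 0 of the 66 list tests passed by camera, and 12 had an unadjusted p under 0.05. The cause was not tested. The strict filter, which leaves fewer members per list, lost the myelinating list in BMP4 against LIF_NOG (adjusted p up to 0.728 over alternatives with matched rows) and in LIF_NOG against Neurosphere (up to 0.947), the synaptogenic list in both BMP4 comparisons, the reactive astrocyte list in BMP4 against Neurosphere, and the neuronal and interferon lists. Median scaling and the realigned authors' values also lost the interferon list, and the mean of probes lost glycolysis and hypoxia genes. By construction the strict filter drops members not detected on every array, such as Opalin, Bcas1 and Trf, which lay under the detection floor in BMP4. Whether this by itself explains the calls it lost was not tested. For the other alternatives the cause was not tested either.

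Splitting the Neurosphere arrays into pairs, which leaves fewer controls by construction, gave 1541 to 1796 genes changed the same way.

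Within 1 row-order set 2314 genes differed between BMP4 and LIF_NOG, 1693 between LIF_NOG and Neurosphere and 3805 between BMP4 and Neurosphere, and 1119 changed the same way. Both the number of arrays and the sets compared differ there, and the cause was not tested. The number of lists that passed was 29.

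The replicate number as a block gave 4829, 3599 and 5918 genes and 25 lists. Of the 24 list calls reported it changed none, and of the named genes it lost Cidea in LIF_NOG against Neurosphere (adjusted p = 0.0506, and 0.0252 to 0.288 over alternatives with matched rows) and changed no other call. Of 12 same-numbered pairs, 7 had a correlation over 0.1, with a range of -0.0546 to 0.261. As the labels give no shared origin and not every pair was over 0.1, the samples were not treated as pairs. Between BMP4 and LIF_NOG all 4 arrays correlated best with their own number (0.126, 0.201, 0.0625 and 0.192), which is a hint from the data and not from the design. Slide as a block was not run, as the files give no slides.

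The raw table with rows as deposited, in which Neurosphere 1 carries the values of other probes, gave 737, 379 and 1435 genes, 22 lists and 259 genes changed the same way. In LIF_NOG against Neurosphere it reversed Olig2 (0.26), Stard4 (0.15) and Fdps (0.76), and 65 other values were weaker. The mixed row orders are the cause by construction.

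The planned use of the authors' values took their rows as deposited, where 6 arrays carry the values of other probes. It gave 461 genes for BMP4 against LIF_NOG, 0 for LIF_NOG against Neurosphere by limma (407 at unadjusted p under 0.05) and 584 for BMP4 against Neurosphere, with 9 lists and 0 genes changed the same way. Of 179 values 12 were the same, 111 were weaker and 56 were reversed, and with rows realigned 177 were the same and 0 were reversed. The mixed row orders are the cause by construction.

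The reversed values in BMP4 against LIF_NOG were those of the astrocyte markers Gfap (-2.58), Aqp4 (-3.88), Slc1a2 (-0.87), Aldoc (-3.60), Gja1 (-2.82) and Slc39a12 (-0.17), and of the BMP targets Id1 (-0.74), Id2 (-0.43) and Id3 (-1.59). Socs3 (-2.40), Pim3 (-0.88), Tfcp2l1 (-0.11), Cd44 (-2.34), Hspb1 (-1.36), Cdkn1a (-1.95), Slc2a1 (-1.68) and Vegfa (-1.04) reversed too. So did Serpinf1 (-0.0305), Diras2 (-0.26), Ccdc3 (-1.19), Kcnc4 (-0.12), Chchd10 (-0.44), Scg2 (-0.21), Dlx2 (-0.78), Olig2 (0.52) and Dcx (4.63).

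In BMP4 against Neurosphere the reversed values were those of Gfap (-0.0410), Serpinf1 (-0.0512), Ccdc3 (-0.22), Cidea (-0.0344), Serpina3n (-0.0042), Rgs9 (-0.40), Rrm2 (2.57), Kcnc4 (-1.83), Chchd10 (-1.26), Diras2 (-1.11) and Cldn11 (0.44). Among astrocyte and reactive genes, Apoe (-0.40), Aqp4 (-1.27), Clu (-0.46), Slc1a2 (-0.65), Aldoc (-3.03), Gja1 (-2.19), S100b (-0.0435), Hspb1 (-0.25), Cd44 (-1.66) and Vim (-4.94) reversed. Id1 (-1.07), Id2 (-0.30), Id3 (-1.60), Id4 (-0.20), Socs3 (-0.44), Tfcp2l1 (-0.0478), Fos (-1.25), Dusp1 (-1.46) and Bcan (-0.98) reversed as well.

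Signal over background limits what the arrays show. Between 38.6% and 42.0% of probes were detected per array, and called genes dim in 1 group have lower bounds only, by the rule given above. The list of microglia and macrophage genes, with 1 measured member, could not be tested, as lists with fewer than 3 measured genes (1 list) were left out.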

Other observations

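Of 10785 genes, 784 passed against Neurosphere in LIF_NOG only and 3069 in BMP4 only, which compares thresholds and not sizes.

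LIF_NOG 2 correlated at most at 0.970 with another LIF_NOG array and at most at 0.957 with a Neurosphere array, whereas the other 3 LIF_NOG arrays correlated at 0.983 or more among each other. Over 925 genes that differ at least 2-fold between Neurosphere and the other LIF_NOG arrays, LIF_NOG 2 lay a median of 53.7% of the way to Neurosphere. Array weights were lowest for LIF_NOG 2 (0.246) and BMP4 4 (0.333).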
